A study of Mus musculus with 6 samples.

How the data were processed

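Gene expression was measured in soleus, a slow postural muscle of the hindlimb, of C57Bl/6 mice that had been hindlimb suspended, a procedure in which the hindlimbs are kept from bearing weight. Per the labels, total RNA was prepared from cryosections on silica columns and 3 microgram were used per array. The labels describe 6 arrays, all of suspended animals, and number them 1 to 6. No unsuspended or reloaded animals were analysed here, so no comparison between conditions was possible. The labels do not say in so many words that each array came from a different animal, and spread between arrays may therefore be partly technical.

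The deposited table holds 1 intensity value per probe and array, for 223 probes. Per the values of the deposited table, the intensities are linear and had been background-subtracted by the authors, since 171 of the 1338 values lie at or below 0 and the lowest is -0.0020. The reference to which the authors scaled these intensities is not given in the sources used here. The deposited arrays share neither a total nor a median. The value for the 28S ribosomal RNA probe is given to fewer decimals than the others. Scanner, background method, spot averaging and array maker are not given in the sources used here. The number of arrays limits the precision, and no counts or depth exist for such data.

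Probes were named through the GEO platform annotation supplied with the table. Of the 223 probes, 205 have 1 gene symbol, 0 have several and 18 are unnamed here. The gene numbers of 204 of the 205 were found in the mouse RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed through that match. The remaining probe, POLB, carries a gene number that the mouse table does not hold and keeps its annotated name. The 205 probes stand for 203 genes, of which 2 (Fn1 and Igf1) have 2 probes each. The probes' genome positions are not given, because the table names no genome build.

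A probe was called measured when its value was above 0 on all 6 arrays. This held for 171 probes, and the other 52 were left out of levels and tests. Measured values were put on the log2 scale without a pseudocount, and each array's median over the measured probes was subtracted. A level of 0 is thus the array median, and 1 unit is a factor of 2. Levels of different probes depend on probe and labelling, so a higher level is not read as more transcript. Levels were ranked across probes only to choose probes and named genes, to filter, to match random lists and to split or curve by level. For a gene with 2 probes the one of higher mean was used in the lists.

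There were 16 gene lists with 502 genes in all, fixed before the data were examined: slow contractile, fast contractile, developmental contractile and denervation, mitochondrial respiration, fatty acid uptake and oxidation, glucose uptake and glycolysis, proteolysis, myogenic regulators and growth factors, extracellular matrix and adhesion, angiogenesis and hypoxia, stress and antioxidant, proliferation and immediate early, blood and vessel cells, immune cells, fat and nerve cells, and reference genes. The genes named were chosen by a rule that was also fixed then. It takes up to 3 measured members per list with the highest mean, the 10 genes with the largest and the 5 with the smallest SD among genes above the median level, which gave 48 genes. Any other gene named below was chosen after its values were seen, and is said to be so.

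Each list with at least 4 measured members (9 lists) was tested in 2 ways against 10000 random lists of the same size drawn from the measured probes and matched on level in 5 bins. The first test compared the list's median SD between arrays, and the second its mean pairwise Pearson correlation over the 6 arrays. The p-values of both list tests are two-sided and count the random lists at least as extreme. They are marked as permutation values below, but probes were redrawn and arrays were not shuffled. They were adjusted by Benjamini-Hochberg over the 9 lists at a threshold of 0.05. Random lists carry array-wide effects as the fixed lists do. Members of a list are not independent of each other, so these p-values describe the 6 arrays and not a population of animals. Of 5 planned correlations between list scores, 3 were run. The others needed the slow contractile list, of which 2 members were measured, against a minimum of 3. A list score is the mean over members of each probe's difference from its own mean. Correlations were tested with all 720 pairings of the 6 arrays, two-sided.

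The list tests were tested on simulated data with the levels of the 171 measured probes and noise with an SD of 0.34, 50 simulations per case, in which the fatty acid list was altered. With its spread multiplied by 0.5, the spread test called it in 49 of 50 simulations. With a shared component of the same SD as the noise, the correlation test called it in 39 of 50 and the spread test in 17 of 50. With no alteration, any of the lists was called by the spread test in 0 of 50 simulations and by the correlation test in 3 of 50. The noise SD of 0.34 is the median SD of the measured probes without replicate 1. With all arrays that median was 0.48, and it was 0.67 for the probes of lowest level and 0.43 for those of highest level. These call rates therefore describe the simulated data only, and do not give the power or false calls of the tests on all arrays.

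Alternatives were the deposited values without centring, quantile normalization, equal array totals, a filter at the 25th percentile of level, no filter, leaving out each array, and other list scores. A lowess curve on level with a span of 0.5, a stricter bound for measured probes, counts of measured probes without each array, and 2 list scores without their lowest probes were added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.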

Results

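The transcripts of a focused set of muscle, metabolic, vascular and matrix genes were measured in suspended mouse soleus on 6 arrays of 223 probes. All 6 arrays belong to the suspended group, so the measurements are the levels of these transcripts in unloaded muscle and how far they varied between arrays. The deposited intensities of an array summed to between 15.3 and 37.5. Replicate 1 had the sum of 37.5, and the other 5 arrays lay between 15.3 and 18.5. The median deposited intensity was 0.0061 on replicate 1 and between 0.0036 and 0.0055 on the others. A value above 0 on all arrays was found for 171 probes, on some arrays for 44 and on none for 8.

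All 6 probed members of the mitochondrial respiration list, all 13 of the glucose uptake and glycolysis list, all 4 of the blood and vessel cell list and all 3 of the proteolysis list were measured on every array. So were 11 of 12 in the fatty acid list, the exception being Lipe, the hormone-sensitive lipase. Among myogenic regulators and growth factors 19 of 24 genes were measured, and Myf5, Igf1r, Fgf2, Fgfr4 and Hgf were not measured on all arrays. In the matrix and adhesion list 20 of 23 genes were measured, and Lamb1, Mmp3 and Mmp9 were at or below 0 on at least 1 array. In the angiogenesis and hypoxia list 16 of 20 were measured, the others being Angpt1, Vhl, Nos3 and Pdgfa. In the proliferation and immediate early list 7 of 11 were measured, the others being Ccna2, Top2a, Junb and Fosl1. Neither of the 2 immune genes probed, Il6 and Il1b, was above 0 on all arrays, each being so on 2 of 6. No gene of the developmental contractile and denervation list was on the array. The stress list had 1 gene probed (Hmox1), the list of fat and nerve cells 1 (Fabp4), and the reference list 5, of which Hprt was not measured on all arrays.

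Slow and fast myosin heavy chain transcripts were both measured in suspended soleus. Myh7, the slow heavy chain, had a level of 6.60 ± 0.48 (SD, n = 6) on the log2 scale relative to the array median. Myoglobin (Mb), the oxygen store of red fibres and the only other slow list member measured, had a level of 6.58 ± 0.25. Of the fast heavy chains, Myh1 (type IIx) was at 6.46 ± 0.28, Myh4 (type IIb) at 5.48 ± 0.26 and Myh2 (type IIa) at 3.32 ± 0.82. The deposited intensity of Myh7 averaged 0.928 ± 0.597 (SD, n = 6) and that of Myh1 0.795 ± 0.333. Without replicate 1 the SD was 0.14 for Myh7, 0.13 for Myh1, 0.34 for Myh2, 0.19 for Mb and 0.17 for Myh4 (n = 5). On replicate 1, Myh2 was 1.85, Myh7 1.12, Myh1 0.62, Myh4 0.52 and Mb 0.46 above the mean of the other arrays on the log2 scale. The median of such differences over all measured probes was then subtracted. The differences of Myh2, Myh7, Myh1, Myh4 and Mb became 1.73, 1.00, 0.49, 0.39 and 0.33 under median centring, equal totals and no centring. They were 1.21, 0.47, 0.05, -0.15 and -0.19 with quantile normalization and 1.65, 0.53, 0.03, 0.04 and -0.14 with a lowess curve on level removed.

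**Figure D1:**
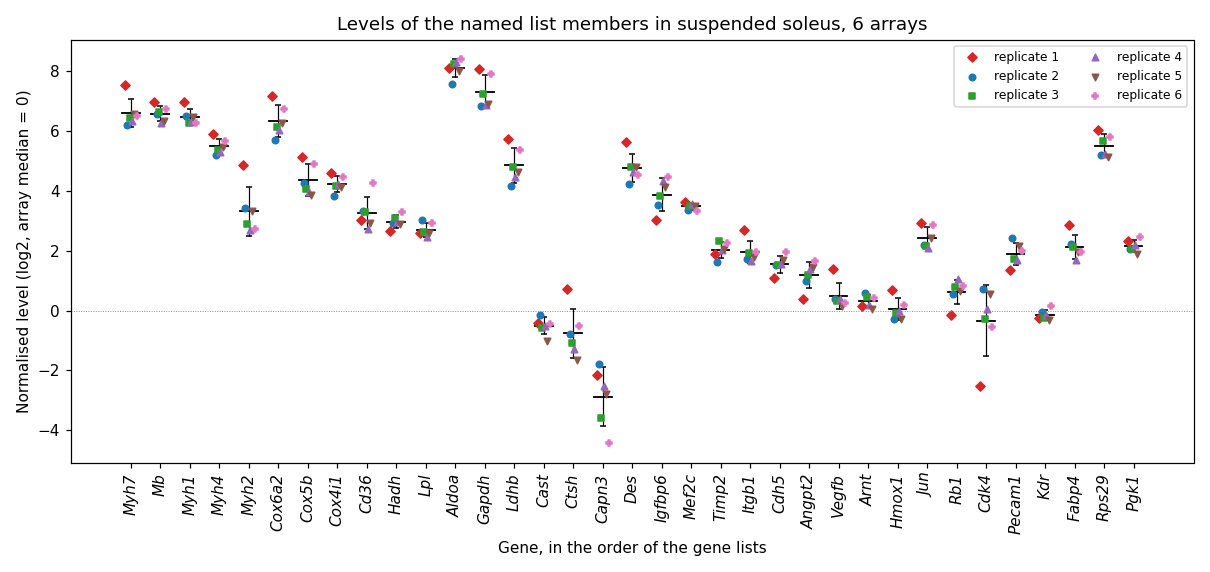
Normalised level (log2, array median at 0) of the named gene list members on each of the 6 arrays. Points are arrays, horizontal bars the mean and vertical bars the SD (n = 6). Replicate 1 lies above the other 5 arrays for Myh7, Myh1 and Myh2 and below them for Cdk4, while Mef2c has an SD of 0.11.

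The fatty acid list had a lower spread than matched random lists with all 6 arrays and median centring, a call lost under most other settings. Cpt1b, which admits long-chain fatty acids to mitochondria, had a level of 0.82 ± 0.09 (SD, n = 6). Acadl, a dehydrogenase of long-chain fatty acid oxidation, was at 1.72 ± 0.13, and Ppara, a nuclear receptor for fatty acids, at 0.09 ± 0.15. The beta-oxidation enzyme Hadh was at 2.97 ± 0.21 and lipoprotein lipase (Lpl) at 2.69 ± 0.22. The fatty acid transporter Cd36 was at 3.25 ± 0.53, and its SD was 0.25 without replicate 6 (n = 5). Named after their values were seen, the remaining members were Pparg at -0.86 ± 0.81, Fabp3 at 0.02 ± 0.51, Acadm at 0.51 ± 0.42 and Ucp3 at 1.18 ± 0.22, besides Fabp4 (SD 0.40). Pparg was at 0.73 on replicate 2 and between -1.44 and -0.87 on the other arrays. The small SDs depended on the scaling. With equal totals and without centring the SD was 0.30 and 0.24 for Cpt1b, 0.29 and 0.35 for Acadl, and 0.22 and 0.38 for Ppara. That of Cpt1b was 0.06 with quantile normalization and 0.03 without replicate 6, and that of Acadl 0.07 without replicate 2. The 11 measured members had a median SD of 0.22, against a median of 0.42 in random lists matched on level. This spread was at the 0.10 percentile of the random lists, with a Benjamini-Hochberg adjusted p = 0.038 over 9 lists (permutation). The call was lost without replicate 1 (adjusted p = 0.53 by permutation, at the 5.96 percentile), and also without replicates 2, 4, 5 or 6 (0.46, 0.056, 0.070 and 0.092). It was lost with quantile normalization (0.26), equal totals (0.52), no centring (0.25), no filter (0.46) and the lowess curve (0.37) as well. No test compared this list with the other metabolic lists.

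The spread of the glucose uptake and glycolysis list and of the mitochondrial respiration list lay within that of random lists. Aldoa, the muscle aldolase, had a level of 8.10 ± 0.30 (SD 0.16 without replicate 2), Gapdh of 7.31 ± 0.55 and Ldhb, the lactate dehydrogenase subunit of oxidative tissue, of 4.86 ± 0.58 (SD, n = 6 each). The related aldolase Aldoc was among the most variable genes, at 1.86 ± 0.76. Pgk1, another glycolytic enzyme, was at 2.16 ± 0.21. Subunits of cytochrome c oxidase were at 6.34 ± 0.53 (Cox6a2), 4.36 ± 0.53 (Cox5b) and 4.23 ± 0.27 (Cox4i1). The members of these lists are called glycolytic and respiratory genes for short, though some lie outside glycolysis and the respiratory chain. The median SD was 0.55 for the 13 glycolytic genes and 0.49 for the 6 respiratory genes, at the 85.4 and 66.5 percentiles of matched random lists. Neither differed from random lists after adjustment (adjusted p = 0.44 and 0.67, permutation).

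Mef2c, a muscle transcription factor, was among the 5 least variable genes above the median level, at 3.48 ± 0.11 (SD, n = 6), with an SD of 0.20 under quantile normalization, 0.27 under equal totals and 0.40 without centring. Vldlr, a lipoprotein receptor on no list, was another, at 1.93 ± 0.17 (SD 0.29 both with equal totals and without centring). Desmin (Des), the muscle intermediate filament protein, was at 4.76 ± 0.48 (SD 0.23 without replicate 1), and Igfbp6, a binding protein of insulin-like growth factors, at 3.87 ± 0.54. Srf, a transcription factor for cytoskeletal genes, was at 1.64 ± 0.89 and kept an SD of 0.85 without replicate 1. For the 19 growth genes the median SD of 0.43 was at the 25.01 percentile of random lists (adjusted p = 0.67, permutation). It was 0.28 without replicate 1, at the 10.3 percentile (adjusted p = 0.53, permutation). Without replicate 3 the same list was at the 0.40 percentile and passed the threshold (adjusted p = 0.048, permutation). In the proteolysis list, the protease inhibitor Cast was at -0.51 ± 0.28 (SD 0.17 without replicate 5), the lysosomal protease Ctsh at -0.76 ± 0.83 (SD 0.45 without replicate 1) and the muscle calpain Capn3 at -2.87 ± 0.98. On replicates 3 and 6 the value of Capn3 did not exceed the size of the array's most negative value, so its level and SD lie partly within background noise.

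The spread of matrix, vessel, proliferation and reference genes did not pass the list test either. The metalloproteinase inhibitor Timp2 was at 2.03 ± 0.26 and the integrin subunit Itgb1 at 1.95 ± 0.38 (SD, n = 6 each). The endothelial genes Pecam1, Cdh5 and Kdr were at 1.89 ± 0.38, 1.55 ± 0.29 and -0.15 ± 0.17. Angpt2, a ligand that destabilises vessels, was at 1.19 ± 0.45, Vegfb at 0.49 ± 0.45 and Arnt, a partner of the hypoxia-inducible factors, at 0.31 ± 0.20. Jun was at 2.44 ± 0.37, the cell cycle regulator Rb1 at 0.62 ± 0.41 and Cdk4 at -0.34 ± 1.18. The haem-degrading enzyme Hmox1 was at 0.04 ± 0.36, and Fabp4, which fat cells and vessels express, at 2.14 ± 0.40 (SD 0.15 with equal totals). Of the reference genes, the ribosomal protein gene Rps29 was at 5.51 ± 0.37 and Ywhaz at 0.75 ± 0.70. Without replicate 1 the SD was 0.55 for Cdk4, whose mean was then 0.10, 0.29 for Ywhaz, 0.26 for Angpt2, 0.20 for Fabp4, 0.19 for Hmox1 and Cdh5, 0.18 for Rb1, 0.14 for Itgb1 and 0.10 for Vegfb (n = 5). The SD of Kdr was 0.10 without replicate 6. On replicate 1 the value of Cdk4 did not exceed the size of the array's most negative value. Median SDs were 0.39 for the 20 matrix genes, 0.39 for the 16 angiogenesis genes, 0.29 for the 4 vessel genes, 0.84 for the 7 proliferation genes and 0.46 for the 4 reference genes. They lay at the 6.23, 9.86, 14.3, 98.1 and 67.7 percentiles of random lists, with adjusted p = 0.38, 0.44, 0.44, 0.17 and 0.67 (permutation). Without replicate 1 the median SD was 0.39 for the proliferation genes and 0.30 for the reference genes. These lay at the 58.9 and 56.7 percentiles (adjusted p = 0.87 for each, permutation). Without centring, the proliferation and vessel lists both passed the threshold (adjusted p = 0.039, permutation).

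In none of the 9 lists did the members correlate across the 6 arrays more, or less, than in matched random lists after adjustment, under the main settings. The mean pairwise correlation was 0.75 for the 4 reference genes, 0.42 for the 6 respiratory genes, 0.28 for the 4 vessel genes and 0.21 for the 13 glycolytic genes. The respiratory value was -0.05 with quantile normalization and 0.83 with only probes above the 25th percentile of level, where it passed the threshold (adjusted p = 0.049, permutation). The mean pairwise correlation was 0.14 for the fatty acid list, 0.09 for matrix, 0.04 for growth, 0.0035 for proliferation and -0.05 for angiogenesis. Over the other settings and left-out arrays it ranged from 0.25 to 0.88 for reference, -0.09 to 0.67 for vessel, 0.10 to 0.48 for glycolytic, 0.03 to 0.46 for fatty acid and 0.03 to 0.42 for matrix genes. The ranges were -0.0035 to 0.47 for growth, -0.18 to 0.20 for proliferation and -0.05 to 0.27 for angiogenesis genes. By permutation, adjusted p-values were 0.24 for the reference, glycolytic and matrix lists, 0.34 for the respiratory, vessel, fatty acid and angiogenesis lists, 0.44 for growth and 0.76 for proliferation. The lowest unadjusted permutation p, and the only one of the 9 under the threshold, was that of the reference list, at 0.050.

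**Figure D2:**
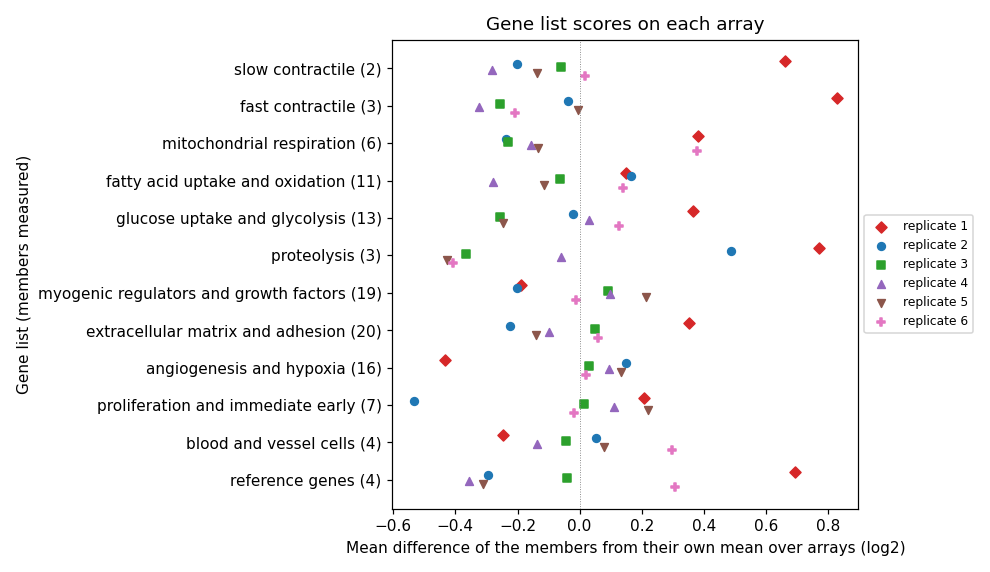
Score of each gene list with at least 2 measured members on each array (log2), as the mean difference of its members from their own mean over the 6 arrays. Replicate 1 has scores of 0.66 for slow and 0.83 for fast contractile genes and of -0.43 for angiogenesis genes, outside the other 5 arrays. Its scores of 0.69 for reference and 0.77 for proteolysis genes also lie above the other 5 arrays. The angiogenesis score is -0.14 without Nos2, left out after its value was seen, and 6 of the 16 members are higher and 10 lower than the mean of the other arrays.

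Respiratory genes were set against 3 other lists to see whether metabolic and matrix programmes varied together between arrays. The respiratory score and the glycolytic score had a Pearson correlation of 0.80 over the 6 arrays (exact permutation p = 0.076, adjusted over 3 pairs 0.11) and a Spearman correlation of 0.71 (exact p = 0.14, adjusted 0.20). With the matrix score the values were 0.77 (exact p = 0.065, adjusted 0.11) and 0.77 (exact p = 0.10, adjusted 0.20). With the fatty acid score they were 0.54 (exact p = 0.32, adjusted 0.32) and -0.03 (exact p = 1, adjusted 1). The fatty acid pair had r = 0.87 without replicate 2, 0.83 without centring, 0.32 with quantile normalization, 0.29 with the lowess curve and 0.26 with equal totals. With the score taken as the median over members its r was 0.84 (exact p = 0.022, adjusted 0.051) and its Spearman correlation 0.89, and with members scaled to unit SD r was 0.80 (exact p adjusted 0.086). Replicates 1 and 6 are the 2 arrays farthest from the median respiratory score, at 0.38 each against -0.24 to -0.13. Without both, which leaves 4 arrays of narrow range, Pearson's r was -0.05 with glycolysis, -0.14 with matrix and -0.72 with fatty acid genes, so the positive values rest on those arrays together. Without replicate 1 alone r was 0.64, 0.57 and 0.40, and without replicate 6 alone 0.84, 0.88 and 0.41. With only probes above the 25th percentile of level, which drops Tfam from the respiratory list, Hk1 and Insr from the glycolytic list and Lama2, Mmp2, Plat, Plaur, Itgav and Cd44 from the matrix list, r was 0.96 with glycolysis and 0.87 with matrix, and both passed the threshold (exact p adjusted over the pairs 0.0083 and 0.029). The glycolysis pair had 0.59, 0.62 and 0.67 and the matrix pair 0.38, 0.53 and 0.61 with quantile normalization, the lowess curve and equal totals. The reference list score was also highest on replicates 1 and 6, at 0.69 and 0.31 against -0.35 to -0.04 on the others. Gapdh and Pgk1 are in both the reference and the glycolytic list. The pairs were not compared with random lists, so joint variation of these programmes cannot be told apart from an array-wide effect.

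Replicate 1 stood apart from the other arrays. Its Pearson correlations with them over the 171 probes were between 0.86 and 0.91, whereas the 10 pairs among the other arrays gave between 0.957 and 0.977. No pair of arrays shared more than 8 identical values, so none was a repeated deposit. Over all measured probes the median SD between arrays was 0.48 with all arrays and 0.34 without replicate 1. An SD below 0.5 was found for 89 of the 171 measured probes with all arrays and for 130 without replicate 1. Among the 48 named genes, some of which were chosen by their SD, the counts were 29 and 42. Among the 10 most variable genes above the median level, Ang (an angiogenin ribonuclease) differed on replicate 1 from the mean of the others by -3.10 on the log2 scale. The corresponding differences were -2.82 for the cytokine receptor Csf2rb2, -2.60 for the vascular endothelial growth factor receptor Flt1, -2.27 for the ephrin Efnb1 and -2.14 for the laminin chain Lama3. The deposited values of these lower genes on replicate 1 ran from 0.0026 (Flt1) to 0.0047 (Csf2rb2 and Lama3). The array's most negative value was -0.0020, so the sizes of their differences depend strongly on the subtracted background. Higher on replicate 1 were Myh2 by 1.85, Cited2 by 1.77 and Ywhaz by 1.59. These 8 genes kept their direction under median centring, no centring, quantile normalization, equal totals and a lowess curve. They were chosen for a large SD. Median centring, no centring and equal totals only shift whole arrays, by less than any of these differences, so no direction could change between them. For each probe the difference of replicate 1 from the mean of the others was taken. The median of these differences over all measured probes moved with the scaling. It went from 0.65 without centring through 0.13 with median centring to -0.45 with equal totals.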

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

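Except for the shuffle test of grid position, every test in this part was set up after the values were seen. A result appears here when, among the 6 arrays, the highest or lowest lies farther from its neighbour than Dixon's critical ratio for groups of this size allows, which chance gives in about 1 group in 20.

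At the level of whole arrays, replicate 1 had the outlying sum of intensities (Dixon's ratio 0.855) and the outlying median correlation with the other arrays (0.821). Its scores were outlying for slow contractile genes (0.683), fast contractile genes (0.723) and angiogenesis and hypoxia genes (0.775), the first of these resting on 2 genes. The last rests on Nos2, whose deposited value of 0.0001 on replicate 1 did not exceed the size of the array's most negative value. Nos2 differed there by -5.77 from the mean of the others, and the size of that difference lies partly within background noise. Without Nos2 the ratio was 0.606, not outlying, and the difference of the list went from -0.52 to -0.17. Differences of replicate 1 from the mean of the others were also taken relative to the median of such differences over all measured probes. They were 0.67 for slow, 0.87 for fast and -0.64 for angiogenesis genes under median centring, equal totals and no centring. Those scalings only shift whole arrays. The values were 0.14, 0.37 and -0.37 with quantile normalization and 0.19, 0.57 and -0.64 with the lowess curve. For angiogenesis genes without Nos2 they were -0.29, -0.13 with quantile normalization and -0.28 with the lowess curve. With quantile normalization and the lowess curve the fast list rested on Myh2 (1.21 and 1.65). Myh1 was then at 0.05 and 0.03 and Myh4 at -0.15 and 0.04. The reference and proteolysis lists, not outlying themselves, rose by more than the slow list under each of these scalings. Reference genes were at 0.71, 0.47 with quantile normalization and 0.57 with the lowess curve, and proteolysis genes at 0.80, 1.00 and 0.78. The score of proliferation and immediate early genes was outlying on replicate 2, which was low (0.682), and no longer so (0.520) without Ccnd1 and Pcna, whose deposited values there were 0.0004 and 0.0008. Of the 48 named genes 12 were outlying, 11 of them on replicate 1. Among those 11, Ang, Csf2rb2, Flt1, Efnb1, Cited2 and Ywhaz were named only for a large SD, and Myh2 partly so. An outlying array raises the SD, so their flags are partly built in by the choice. High on replicate 1 were Myh7 (0.729), Myh1 (0.638), Myh2 (0.659), Itgb1 (0.693), Vegfb (0.807), Cited2 (0.721) and Ywhaz (0.627). Low on it were Ang (0.729), Csf2rb2 (0.693), Flt1 (0.824) and Efnb1 (0.634). Their deposited values there lay between 0.0026 and 0.0047, near the size of the array's most negative value of -0.0020. Cpt1b was high on replicate 6 (0.767), within an SD of 0.09. Over all 171 measured probes 27 were outlying, 23 of them on replicate 1, of which 13 were high and 10 low.

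The SD over probes of replicate 1's difference from the mean of the other arrays was 1.31, against at most 0.70 for any other array, a ratio of 1.88 (95% bootstrap interval over probes 1.48 to 2.25). Agtr2, named after its values were seen, and Nos2 contribute to the 1.31, with differences of -7.76 and -5.77. Their deposited values of 0.0001 on replicate 1 did not exceed the size of the array's most negative value. Over the 43 probes of highest level the SD was 0.88, against at most 0.50 for any other array. Ang, Csf2rb2, Flt1, Efnb1 and Lama3, which were low on replicate 1, are not among those 43 probes. The ratio stayed above 1 after each of 3 technical explanations was allowed for. This argues only against each of them as the whole of replicate 1's larger SD. A partial cause would leave the ratio above 1 as well, and replicate 1 was picked for standing apart. Each explanation was judged by whether the bootstrap interval stayed above 1. That interval treats probes as independent and holds no spread between arrays. The bound of 1 replaced one of 1.5, set before the ratios were seen. All 3 ratios exceed 1.5, but the intervals for level and background do not clear it. The ratio was 1.84 (1.44 to 2.22) after a lowess curve on level was removed from every array, 1.77 (1.30 to 2.14) over the 43 probes of highest level, where a wrong background would matter little, and 1.83 (1.503 to 2.17) after grid rows and columns were removed. Part of the pattern may follow position on the grid, since rows and columns accounted for 30.6% of the variance of replicate 1's differences against a median of 19.1% in 10000 shuffles (one-sided permutation p = 0.016), but related genes sit close together there, replicates 3, 5 and 6 had 28.6%, 38.9% and 35.7%, and 4 of the 6 arrays had a permutation p below 0.05. The other arrays' differences were taken from means that include replicate 1. Their SDs and grid shares are therefore not independent of its pattern. RNA quality, labelling and a true difference of this animal stay open as untested, and the design has no second group in which a biological explanation could be tested.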

How the results depend on the processing

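All alternatives were fixed before the data were examined, except the lowess curve, the stricter bound for measured probes, the counts of measured probes without each array and 2 list scores without their lowest probes. No paired analysis was possible because there is only 1 group. The low spread of the fatty acid list (0.10 percentile) lost its call at the 5.11 percentile with equal totals, 1.61 with the lowess curve, 11.4 with no filter, 2.02 with quantile normalization and 4.94 without centring, and lay between 0.22 and 5.96 with each array left out. Calls appeared for the spread of vessel genes (0.41) and proliferation genes (99.8) without centring, and of growth genes without replicate 3 (range over left-out arrays 0.40 to 47.9). With the 25th percentile filter, calls appeared for the correlation of respiratory genes (99.7 percentile) and for the respiratory score with glycolysis (r = 0.96) and matrix (r = 0.87). Lists with no call crossed the middle of the random lists as follows. For spread, glycolytic genes went from the 85.4 to the 38.4 percentile with equal totals, 43.6 with the lowess curve, 25.4 with the filter and 13.2 with quantile normalization. Respiratory genes went from 66.5 to 26.8, 34.8 and 48.1 with equal totals, lowess and quantile (45.7 to 68.3 over left-out arrays), and reference genes from 67.7 to 37.9, 14.4 and 28.1. For correlation, the angiogenesis list went from 13.2 to 87.2 with equal totals and 69.9 with lowess, vessel genes from 86.8 to 27.1 without centring (44.5 to 92.0 over left-out arrays), and with equal totals matrix genes from 96.3 to 27.4 and fatty acid genes from 88.0 to 32.0. Respiratory genes went from 90.1 to 42.4 with quantile normalization, and proliferation genes from 61.8 to 41.6 with no filter, 8.16 with the filter and 46.6 without centring (15.96 to 83.9 over left-out arrays). The cause of these changes was not tested. The median SD of 0.48 ranged from 0.34 (without replicate 1) to 0.52 over left-out arrays. Replicate 1's median correlation with the others rose from 0.88 to 0.957 on linear values, which a few bright probes dominate by construction. The count of measured probes stayed between 134 (above the size of each array's most negative value) and 182 (above 0 on at least 5 arrays). The SD of a named gene depended on the scaling, moving by over 1.5 times for 22 of 48 genes with equal totals, 16 without centring and 14 with quantile normalization. Low signal limits what can be said: the median SD was 0.67 over the 57 probes of lowest level and 0.43 over the 57 of highest level.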

Other observations

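The genes named in this part were chosen after their values were seen, except Lama3, Srf, Aldoc, Cd36, Fabp4 and the contractile genes, and all tests here were set up after the data were seen. The 2 probes of Igf1, the insulin-like growth factor, sit apart on the grid and were annotated from different sequence records. Their levels had a Pearson correlation of 0.997 over the 6 arrays (exact permutation p = 0.0014, adjusted over 3 correlations 0.0042) and a Spearman correlation of 1 (exact p = 0.0028). Pearson's r was 0.996 without the 2 arrays farthest from the median. Both were lower on replicate 1 than the mean of the others (-1.27 and -0.91, log2), as was Igf2 (-1.26). The 2 probes of fibronectin, Fn1, carry the same sequence record yet differed: one was above 0 on 1 of 6 arrays and the other on all 6, with deposited intensities from 0.0083 to 0.0292.

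Among the 5 arrays other than replicate 1, the most variable genes above the median level were Lama3, with a range of 6.37-fold after median centring, Srf (5.08-fold), Aldoc (4.03-fold), Pole2 (3.32-fold) and Cd36 (2.85-fold). Without the array farthest from the median of these 5, the ranges were 4.88-fold for Lama3 (replicate 6 left out), 2.90-fold for Srf (replicate 2), 1.75-fold for Aldoc (replicate 6), 1.66-fold for Pole2 (replicate 4) and 1.497-fold for Cd36 (replicate 6). Of the 10 most variable genes with all arrays, 3 were also among the 10 most variable without replicate 1. Pparg, a regulator of fat storage, was 1.98 higher on replicate 2 than the mean of replicates 3 to 6 on the log2 scale (SD of those 4 arrays 0.22), while Fabp4, which Pparg is known to control in fat cells, was 0.30 higher (SD 0.17). Myod1 and Myog, the myogenic factors, were at -1.15 ± 0.25 and -1.20 ± 0.29 (SD, n = 6). Myod1 was at -1.58 on replicate 2 and between -1.19 and -0.83 on the other arrays. Myog was at -0.66 on replicate 6 and between -1.49 and -1.18 on the other arrays. The unnamed probe of highest intensity had deposited values from 3.99 to 15.6 and took between 26.1% (replicate 6) and 42.8% (replicate 2) of all positive signal.

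A trade-off between slow and fast fibre transcripts from animal to animal was asked for as a hypothesis, with the slow score from Myh7 and Mb and the fast score from Myh1, Myh2 and Myh4. The scores correlated at r = 0.91 (exact permutation p = 0.079, adjusted over 3 correlations 0.12; Spearman 0.54, exact p = 0.30). Pearson's r was 0.02 without replicate 1 (exact p = 0.95) and -0.80 without replicates 1 and 4, so the positive value rests on replicate 1 and neither a trade-off nor a joint change can be read from these arrays.

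Whether the authors divided each array by its 28S ribosomal RNA value was examined as a possible explanation of the unequal totals. The log2 sum of intensities and the log2 28S value had r = -0.21 over the 6 arrays (exact permutation p = 0.82, adjusted 0.82; Spearman -0.03, exact p = 1). The sum holds the 28S value itself (2.04 of 18.3 on replicate 2), which works against a negative r. Without the 2 arrays farthest from the median 28S value r was 0.06. With 6 arrays this leaves the scaling open.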
